A study of Homo sapiens with 6 samples.

How the data were processed

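The study measured RNA in HepG2 cells, an established human liver cancer line. The cells were infected with a lentivirus carrying either a control short hairpin RNA (sh-control, 3 libraries) or a hairpin against circFTO (sh-circFTO, 3 libraries). circFTO is a circular RNA made from the FTO gene. Per the labels' protocols, total RNA was extracted with a column kit, libraries were made with a SMARTER mRNA-Seq kit, and the cells were kept in serum-supplemented DMEM. The labels of these 6 libraries name no serine or glycine deprivation, and they call the cells epithelial in one field and mesenchymal in another. They do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

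One table of the whole series was used. Per the file headers and values, it holds deposited raw counts per Ensembl gene for each library, and FPKM values that the authors computed from them. The deposited FPKM values equalled the count divided by exonic gene length and by the library's total count, and 0 of 363630 values differed from this by more than 0.00501. The aligner, the counting tool, its use of strand and the annotation release are not given in the sources used here. The submitters' processing notes list the genome builds GRCm38, mm10 and hg18, yet the gene identifiers are human. Of 60605 genes, 58337 were in GENCODE release 29 on GRCh38, and 56808 of these lay on the same chromosome with both ends within 5000 bp, so coordinates are given on GRCh38. Reads of pseudogenes, multigene families and overlapping or antisense genes could be split in the authors' counting, so such genes are uncertain. The counts are per gene and do not measure circFTO itself.

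Groups came from the labels. The test written before the data were examined assumed that only FPKM had been deposited. It provided that edgeR's quasi-likelihood test would become the main test if counts were present, and they were. Genes with FPKM of at least 1 in at least 3 libraries were kept (12865 genes). Library sizes were the totals over all genes, scaled by TMM, and edgeR 4.0.16 in R 4.3.3 compared the groups with Benjamini-Hochberg adjustment at 0.05. Levels are TMM-normalised CPM, given as mean ± SD over n = 3 libraries, and fold changes are log2 values of sh-circFTO against sh-control with standard errors (SE). Where a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where it held 1 to 3 counts, the count ratio is given with its exact 95% interval. Both cover counting error only.

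The 35 gene lists were fixed before the data were examined, and 34 had at least 3 tested genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, with fry, and with Fisher's exact test against the tested genes. Terms of the biological process annotation in the deposited table, with 10 to 200 tested genes, were tested with camera in the same way. The genes named were FTO, MYC, PHGDH, PSAT1, PSPH, SHMT1 and SHMT2 whatever their result, the 10 largest rises and 10 largest falls among genes with a symbol that passed the test and whose 3 libraries all lay on one side of the other 3, and up to 4 members of each list with the smallest adjusted p. The table has no gene type column, so the rule took genes with a symbol, which includes pseudogenes and non-coding RNAs. Some genes that the rule takes are not reported here.

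Depth ran from 13361333 to 16178079 counts per library. On data simulated from the real means and library sizes for 12865 genes, the same fit recovered 40.0% of 50 genes changed 1.25-fold, 78.0% of 50 changed 1.5-fold, 90.0% of 50 changed 2-fold and 100% of 50 changed 4-fold. Of 165 calls there, 11 (6.67%) were unchanged genes. Replicates were compared before averaging: the chi-square per degree of freedom between libraries of one group was 2.06 to 4.71, against 101 to 115 between groups, so no library was a copy of another. The loess trend of fold change on GC content and length used 12801 of the tested genes (99.5%) and a span of 0.3.

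Alternatives fixed before the data were examined were other pseudocounts, filters and scalings, no variance trend, library weights, the replicate number as a block, DESeq2 1.42.0, an estimated correlation, and each library left out. The pseudocount, TPM, median-of-ratios, variance trend and weight alternatives ran within a limma fit of log2(FPKM + 1), where folds of low genes are understated. That limma fit, library size without scaling, edgeR with median-of-ratios factors and the removal of the GC and length trend were added after a first look at the fold changes and counts of calls.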

Results

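The series holds 6 RNA-seq libraries of HepG2 cells, 3 with a control hairpin and 3 with a hairpin against circFTO. Total counts ran from 14932270 to 16178079 over the sh-control libraries and from 13361333 to 15809084 over the sh-circFTO libraries. Mitochondrially encoded genes took 7.94% ± 0.199 of counts in sh-control and 6.59% ± 0.147 in sh-circFTO, and the 50 most abundant genes took 18.5% ± 0.262 and 14.8% ± 0.104. For both shares the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give.

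The comparison asks what a knockdown of circFTO changed in the transcriptome. The series title names c-Myc as the inducer of circFTO and names serine and glycine, so the FTO gene, MYC and the enzymes of serine and glycine synthesis come first. The level of FTO, which encodes an RNA demethylase and from whose exons circFTO is made, was 57.4 ± 1.89 CPM in sh-control and 57.1 ± 1.97 CPM in sh-circFTO. Its 3 sh-control libraries held 2515 counts in total and its 3 sh-circFTO libraries 2643. The log2 fold change was -0.01 (SE 0.0603, adjusted p = 0.937 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Gene-level counts do not measure circFTO itself, and the libraries were made with an mRNA-Seq kit. Whether the hairpin lowered circFTO cannot be read from this value. With library size as the only scaling the sign turned, to 0.14 with an adjusted p of 0.0413 in edgeR.

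MYC, a transcription factor that drives growth, fell from 267 ± 12.4 to 180 ± 4.74 CPM. PHGDH, the first enzyme of serine synthesis from a glycolytic intermediate, fell from 252 ± 16.1 to 31.9 ± 0.228 CPM. The next enzymes of that pathway fell too: PSAT1 from 693 ± 21.6 to 244 ± 1.56 CPM and PSPH from 132 ± 4.31 to 54.7 ± 3.28 CPM. SHMT2 and SHMT1, the mitochondrial and cytosolic enzymes that interconvert serine and glycine, fell from 482 ± 8.58 to 171 ± 0.224 CPM and from 58.3 ± 0.0451 to 25.7 ± 0.984 CPM. On the log2 scale the changes were -0.57 for MYC (SE 0.0433), -2.98 for PHGDH (SE 0.0553), -1.51 for PSAT1 (SE 0.0387), -1.27 for PSPH (SE 0.0549), -1.50 for SHMT2 (SE 0.0393) and -1.18 for SHMT1 (SE 0.0691). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.22e-12 for MYC and between 9.28e-27 and 3.33e-15 for the 5 enzymes, and all 3 sh-circFTO libraries lay below all 3 sh-control libraries for each. On GRCh38, FTO (ENSG00000140718) lies on chromosome 16 from 53701692 to 54158512, MYC (ENSG00000136997) on chromosome 8 from 127735434 to 127742951 and PHGDH (ENSG00000092621) on chromosome 1 from 119648411 to 119744218.

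**Figure D1:**
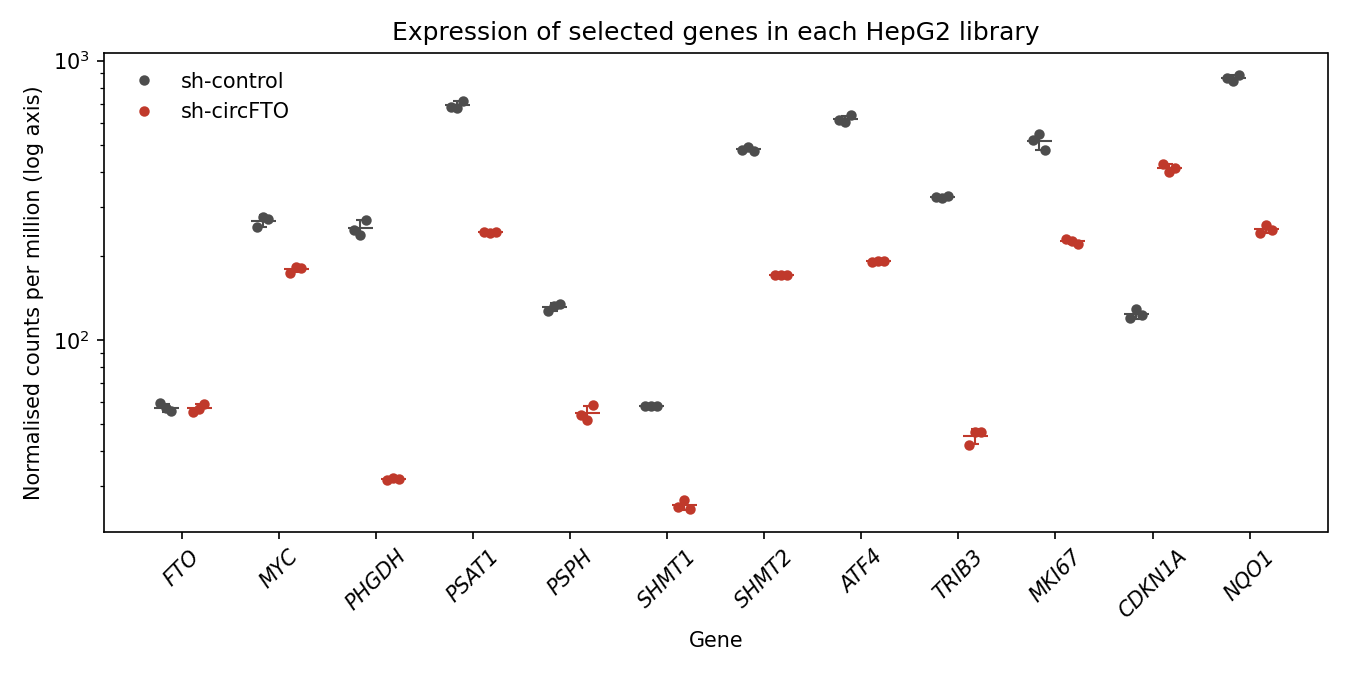
Normalised counts (CPM; vertical, log axis) of 12 genes in each of the 6 libraries; points are libraries, horizontal marks are group means and bars are SD over n = 3. FTO overlaps between the groups, CDKN1A is higher in sh-circFTO and the other 10 genes are lower.

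Across the transcriptome, 8969 of 12865 tested genes (69.7%) passed the test, 4490 higher and 4479 lower in sh-circFTO, and 910 were higher and 980 lower by at least 2-fold. The groups did not overlap for 9193 genes (71.5%), where chance gives 10%. These directions are relative to the median gene: with library size as the only scaling the median log2 fold change moved by 0.145, and the split became 5700 higher and 3471 lower (62.2% of calls higher, against 50.1%).

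The largest rises were in genes close to absent from sh-control. MYH15, a myosin heavy chain, had 0 counts over the sh-control libraries and 539 over the sh-circFTO libraries, at least 170-fold higher, and CCDC70 had 0 and 190, at least 60.0-fold higher. ARHGDIB had 2 and 325 counts (count ratio 154, 95% interval 42.3 to 1278), and KRT13, an epithelial keratin, had 1 and 185 (175, 31.1 to 6965). FLNC, a muscle filamin, rose from 0.113 ± 0.0373 to 13.6 ± 0.356 CPM, and ASB2, a ubiquitin ligase subunit, from 0.297 ± 0.108 to 23.3 ± 0.999 CPM. The unitary pseudogene MYH16 rose from 0.163 ± 0.111 to 13.9 ± 1.45 CPM and the non-coding LINC01173 from 0.278 ± 0.192 to 16.01 ± 1.39 CPM. LINC02137 had 1 and 94 counts (ratio 89.1, 15.6 to 3557). HMGB1P3, a processed pseudogene whose reads could come from HMGB1, had 0 and 32 counts, at least 10.1-fold higher.

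Among the largest falls were SPP1, the secreted protein osteopontin, from 634 ± 22.7 to 41.7 ± 4.06 CPM, and GLRX5, a mitochondrial glutaredoxin of iron-sulfur cluster assembly, from 102 ± 3.89 to 8.02 ± 0.947 CPM. The log2 fold change was -5.28 for the glycosyltransferase gene FUT1, -5.05 for the Wnt antagonist DKK4 and -4.05 for the homeobox gene HOXD1. It was -3.60 for G6PC1, the catalytic subunit of glucose-6-phosphatase, -3.29 for PPARGC1A, a coactivator of mitochondrial and gluconeogenic genes, -3.57 for LGI1 and -3.43 for the aldo-keto reductase AKR1B10. RNU1-75P, a small nuclear RNA pseudogene, had 13 counts over sh-control and 1 over sh-circFTO (count ratio 13.7, 95% interval 2.06 to 583), and its call was lost without sh-circFTO replicate 3 (adjusted p = 0.0556 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

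In the list of serine, glycine and one-carbon enzymes, 17 of 25 tested genes fell and 2 rose, the same numbers when adjusted over the list alone (16 and 4 with library size only). Besides PHGDH, PSAT1 and SHMT2, the mitochondrial folate enzyme MTHFD2 fell from 285 ± 12.7 to 80.8 ± 2.22 CPM. The list's median was -0.47 and camera called it lower (adjusted p = 2.48e-08), a call lost at adjusted p = 0.0651 with an estimated correlation. The list of ATF4, the transcription factor of the amino acid response, and its targets had 22 of 27 genes lower and 3 higher, also when adjusted over the list alone, with a median of -1.49. ATF4 itself fell from 618 ± 16.8 to 192 ± 0.877 CPM, the pseudokinase TRIB3 from 326 ± 2.97 to 45.3 ± 2.78 CPM, the glutamine transporter SLC1A5 from 208 ± 7.98 to 39.2 ± 2.80 CPM and PCK2 from 388 ± 3.79 to 121 ± 0.865 CPM. Camera called this list lower (adjusted p = 2.48e-21), and it held at adjusted p = 0.0129 with an estimated correlation. Of 20 aminoacyl-tRNA synthetases, which charge tRNAs, 15 fell and 3 rose, also when adjusted over the list alone, among them GARS1 (-1.55), YARS1 (-1.48), IARS1 (-1.15) and AARS1 (-1.14). Their camera adjusted p was 1.76e-07, and adjusted p = 0.0651 with an estimated correlation.

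Cell division genes fell together. Of 29 G2/M and mitosis genes, 28 fell, also when adjusted over the list alone, with a median of -1.13. PLK1, a mitotic kinase, fell from 264 ± 16.5 to 89.2 ± 1.47 CPM and the proliferation marker MKI67 from 514 ± 33.3 to 226 ± 4.49 CPM, and CENPF and TPX2 changed by -1.21 and -1.05 on the log2 scale. Camera gave adjusted p = 2.05e-20, and adjusted p = 0.0177 with an estimated correlation. Of 30 G1/S and replication genes 25 fell and 1 rose, also when adjusted over the list alone (22 and 3 with library size only). MCM3, CDT1 and TK1 changed by -1.50, -2.30 and -1.33, and CCND1, which encodes cyclin D1, rose by 1.04. Camera gave adjusted p = 7.56e-06 and adjusted p = 0.0651 with an estimated correlation. Among 26 p53 target genes 20 rose and 3 fell (21 and 3 adjusted over the list alone). The cell cycle inhibitor CDKN1A rose from 124 ± 4.80 to 412 ± 13.5 CPM, and TP53I3, RRM2B and TP53INP1 rose by 2.39, 1.54 and 1.44 on the log2 scale. Camera gave adjusted p = 7.61e-07 and adjusted p = 0.0651 with an estimated correlation. Of 20 apoptosis regulators 15 rose and 4 fell, also when adjusted over the list alone, with MCL1, CASP8 and BAK1 higher by 0.79, 1.09 and 1.37 (adjusted p = 0.00160, and adjusted p = 0.142 with an estimated correlation).

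**Figure D2:**
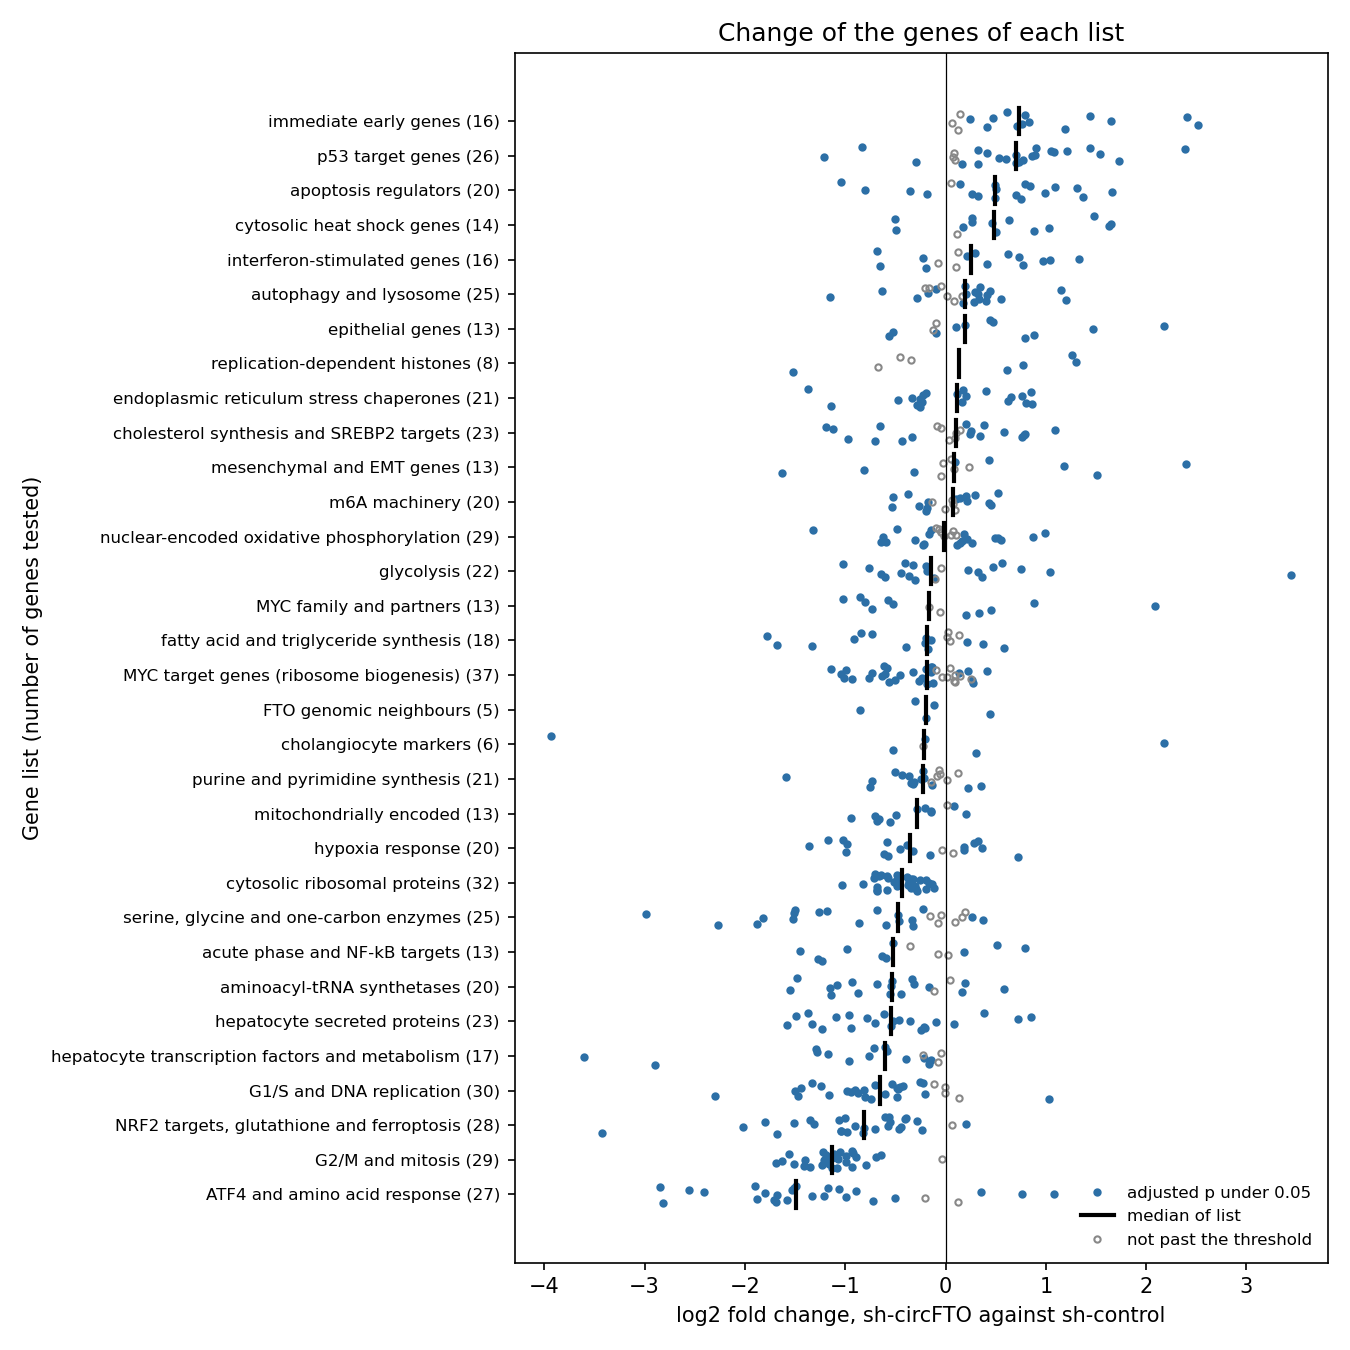
Log2 fold change of sh-circFTO against sh-control (horizontal) for the tested genes of each list with at least 5 of them (vertical); filled points passed the test, open points did not, and black bars are list medians. Medians run from -1.49 for the ATF4 list to 0.74 for immediate early genes.

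The MYC family list went both ways, with 5 of 13 genes higher and 6 lower, and adjusted over the list alone the same. MXD1, a repressor that competes with MYC for its partner MAX, rose from 23.3 ± 3.01 to 99.2 ± 5.82 CPM, MXD4 and MLXIPL changed by 0.88 and -0.73 on the log2 scale. Its median was -0.17 and its mean -0.06, while camera's direction was higher (adjusted p = 0.861). Of 37 MYC targets in ribosome biogenesis 23 fell and 5 rose, also when adjusted over the list alone, but with library size as the only scaling 15 fell and 9 rose. NPM1 and NCL, abundant nucleolar proteins, changed by -1.04 and -1.02, and TBRG4 and PA2G4 by -1.14 and -0.73. Camera gave adjusted p = 0.00454 and adjusted p = 0.212 with an estimated correlation. All 32 cytosolic ribosomal protein genes tested fell (27 with library size only), also when adjusted over the list alone, with a median of -0.43; RPL4, RPL5, RPL3 and RPS2 changed by -1.03, -0.82, -0.69 and -0.71. Camera gave adjusted p = 3.00e-07 and adjusted p = 0.417 with an estimated correlation. Mitochondrially encoded genes, whose share of counts also fell, had 10 of 13 lower and 2 higher, also when adjusted over the list alone (7 and 3 with library size only); MT-CO2, MT-CO1, MT-CO3 and MT-ATP6 changed by -0.94, -0.67, -0.71 and -0.55 (adjusted p = 0.00936, and adjusted p = 0.417 with an estimated correlation).

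Of 28 NRF2 target, glutathione and ferroptosis genes 26 fell and 1 rose, also when adjusted over the list alone (26 and 2 with library size only), with a median of -0.82. Besides AKR1B10, the glutathione peroxidase GPX2 fell from 563 ± 29.8 to 139 ± 1.24 CPM, the quinone reductase NQO1 from 866 ± 22.6 to 249 ± 7.49 CPM and ACSL4 from 416 ± 17.2 to 129 ± 3.74 CPM. Camera gave adjusted p = 8.81e-19, and the call held at adjusted p = 0.0298 with an estimated correlation. The ATF4, G2/M and NRF2 lists were the 3 that held with an estimated correlation, of 21 called by camera. Under that setting camera's p rose even where the estimate lay below the preset 0.01. For the fatty acid list (estimate -0.0260) camera's unadjusted p went from 0.000438 to 0.0190. For the epithelial list (estimate -0.0295) it went from 0.00299 to 0.0348. A call lost under that setting, for a list or an annotation term, therefore does not by itself show correlated genes. Fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, called 27 of 34 lists, among them all 21.

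Liver genes were mostly lower. Of 23 secreted hepatocyte proteins 19 fell and 4 rose, also when adjusted over the list alone. The apolipoprotein gene APOB fell from 7586 ± 386 to 2528 ± 118 CPM, and AHSG, ITIH2 and RBP4 changed by -1.23, -1.09 and -1.49 (adjusted p = 5.50e-08 by camera, and adjusted p = 0.142 with an estimated correlation). Of 17 hepatocyte transcription factors and metabolic enzymes 14 fell (15 adjusted over the list alone, and 11 with library size only, where 1 rose): ASS1, a urea cycle enzyme, fell from 116 ± 2.15 to 15.6 ± 1.33 CPM, the nuclear receptor HNF4A from 262 ± 6.71 to 116 ± 1.35 CPM, and CYP27A1 and NR1H4 changed by -0.97 and -1.29 on the log2 scale (adjusted p = 2.14e-05, and adjusted p = 0.0651 with an estimated correlation). Fatty acid and triglyceride synthesis had 11 of 18 genes lower and 3 higher, also when adjusted over the list alone (7 and 7 with library size only), with GPAM, ACSL3 and SCD at -1.78, -1.33 and -0.84 (adjusted p = 0.00114, and adjusted p = 0.0651 with an estimated correlation). Of 13 acute phase and NF-kB genes 7 fell and 3 rose, also when adjusted over the list alone, with ORM1, CCL20, ICAM1 and ORM2 at -1.45, -1.23, -0.63 and -0.99; ORM1 and ORM2 are near-identical copies whose counts are uncertain. Their adjusted p was 0.0482, and adjusted p = 0.452 with an estimated correlation. Hypoxia genes had 12 of 20 lower and 6 higher, also when adjusted over the list alone (9 and 7 with library size only), with LOX, SLC2A1, VEGFA and P4HA1 at -1.36, -1.02, -1.17 and -0.98 (adjusted p = 0.00818, and adjusted p = 0.119 with an estimated correlation).

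Cytosolic heat shock genes had 11 of 14 higher and 2 lower, also when adjusted over the list alone. The chaperone HSP90AA1 rose from 1056 ± 45.3 to 2164 ± 43.8 CPM, and HSPH1, HSPA1A and HSPA1B, the last 2 near-identical copies with uncertain counts, rose by 1.48, 1.63 and 1.65 (adjusted p = 7.28e-06, and adjusted p = 0.0651 with an estimated correlation). Of 16 immediate early genes 13 rose, also when adjusted over the list alone, among them the transcription factor genes KLF6 and JUNB by 1.44 and 1.65 and the phosphatase gene DUSP1 by 1.19 (adjusted p = 2.98e-06, and adjusted p = 0.0651 with an estimated correlation). Epithelial genes had 8 of 13 higher and 3 lower, also when adjusted over the list alone (8 and 2 with library size only). KRT19 rose by 2.18, JUP by 1.47 and CLDN4 by 0.88, and EPCAM changed by -0.52 (adjusted p = 0.00636, and adjusted p = 0.0985 with an estimated correlation).

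Markers of other cell types did not move one way. Of 3 endothelial markers tested TIE1 rose from 4.03 ± 0.107 to 51.4 ± 0.956 CPM, PECAM1 rose from 7.65 ± 2.21 to 12.2 ± 1.22 CPM and ENG changed by -0.22, a call lost with library size only and without sh-control replicate 2, sh-circFTO replicate 1 or sh-circFTO replicate 2 (adjusted p = 0.0267 by camera, and adjusted p = 0.142 with an estimated correlation). Of 3 macrophage and blood markers LYZ fell from 1012 ± 53.4 to 198 ± 1.61 CPM and FCER1G rose by 0.99, a call lost without sh-control replicate 1, sh-control replicate 3, sh-circFTO replicate 2 or sh-circFTO replicate 3 (camera lower, adjusted p = 0.00637, and adjusted p = 0.107 with an estimated correlation). ACTA2, the 1 fibroblast marker tested, was at -0.04 (SE 0.0589, adjusted p = 0.540 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and on TPM limma called it higher by 0.17 (adjusted p = 0.0156). Of 6 cholangiocyte markers 2 rose and 3 fell (2 and 4 adjusted over the list alone, 2 and 2 with library size only), with SPP1 at -3.93 and ANXA4 at 0.31 (camera adjusted p = 0.344). Of 13 mesenchymal genes 5 rose and 3 fell (4 and 3 adjusted over the list alone, 8 and 3 with library size only), with CCN2 and FN1 at -1.63 and -0.81 and CCN1 and TAGLN at 1.51 and 2.40; its median was 0.08 and its mean 0.24, while camera's direction was lower (adjusted p = 0.996).

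The remaining lists were not called by camera, whose adjusted p is given for each. Of the lists camera did not call, fry called 6: interferon-stimulated genes higher (adjusted p = 6.55e-05), autophagy genes higher (adjusted p = 0.0113), and purine and pyrimidine synthesis (adjusted p = 0.00196), cholangiocyte markers (adjusted p = 0.000795), glycolysis (adjusted p = 0.0426) and the FTO neighbours (adjusted p = 0.0113) lower. With library size only fry called 32 lists, 25 of them as before, and it turned glycolysis to higher (adjusted p = 0.00197) and did not call the FTO neighbours (adjusted p = 0.368). Adjusted over the list alone, the counts that follow were the same, except for autophagy. Glycolysis had 8 of 22 genes higher and 12 lower (9 and 9 with library size only): HK1, a hexokinase, rose from 4.23 ± 0.232 to 45.9 ± 1.29 CPM and PGAM1 by 0.75, while SLC2A1 and GAPDH changed by -1.02 and -0.60 on the log2 scale (median -0.15, mean 0.08, direction lower, adjusted p = 0.884). Purine and pyrimidine synthesis had 13 of 21 lower and 2 higher (8 and 4 with library size only), with IMPDH2, PAICS, DUT and PFAS at -1.59, -0.36, -0.74 and -0.43 (adjusted p = 0.0909). Cholesterol synthesis had 10 of 23 higher and 7 lower (14 and 6 with library size only), with SC5D at -1.19 (adjusted p = 0.920). Endoplasmic reticulum chaperones had 11 of 21 higher and 10 lower (11 and 6 with library size only), with HSPA5 and DNAJB11 at 0.66 and 0.80 and XBP1 and CALR at -1.37 and -1.14 (median 0.12, mean 0.04, direction lower, adjusted p = 0.982). Nuclear-encoded oxidative phosphorylation had 11 of 29 higher and 10 lower (14 and 6 with library size only), with NDUFV2 and NDUFB3 at 0.99 and 0.87 and SDHD and UQCRC1 at -1.33 and -0.48, and its median turned from -0.02 to 0.13 with library size only (adjusted p = 0.978). Autophagy and lysosome genes had 14 of 25 higher and 5 lower (14 and 6 adjusted over the list alone, 17 and 3 with library size only), with ATP6V0D1 and MCOLN1 at 1.20 and 1.15 and CTSD and LAMP2 at -1.16 and -0.64 (adjusted p = 0.405). Interferon-stimulated genes had 9 of 16 higher and 4 lower (11 and 2 with library size only), with ISG15, OAS1 and ISG20 at 1.04, 0.73 and 1.33 and IFI35 at -0.66 (adjusted p = 0.318). The m6A machinery, to which FTO belongs, had 8 of 20 higher and 7 lower (12 and 4 with library size only), with ZC3H13 and IGF2BP3 at 0.52 and 0.46 and IGF2BP1 and YTHDC2 at -0.54 and -0.52 (adjusted p = 0.920). Of 5 genes beside FTO on chromosome 16, CHD9 rose by 0.44 and 4 fell, among them IRX3 at -0.85, RPGRIP1L at -0.31 and AKTIP at -0.20, and with library size only 1 fell (adjusted p = 0.884). The call of AKTIP was lost without sh-control replicate 3, sh-circFTO replicate 1 or sh-circFTO replicate 2, and that of RPGRIP1L without sh-control replicate 1 or sh-circFTO replicate 3. Replication-dependent histones had 4 of 8 higher and 1 lower, with H2BC12, H2AC6 and H2BC5 at 1.30, 0.77 and 1.26 (median 0.13, mean 0.12, direction lower, adjusted p = 0.845).

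Fisher's exact test, with the tested genes as background, called 27 of 68 combinations of list and direction, 16 with more called genes than chance gives and 11 with fewer. Calls of lower genes were enriched among ribosomal proteins (32 against 11.1 by chance, adjusted p = 1.37e-13), G2/M genes (28 against 10.1, adjusted p = 9.17e-11) and NRF2 targets (26 against 9.75, adjusted p = 4.42e-09). Some lists that camera called did not pass Fisher's test in camera's direction. These were fatty acid synthesis (11 lower against 6.27, adjusted p = 0.0609), hypoxia (12 lower against 6.96, adjusted p = 0.0733) and acute phase genes (7 lower against 4.53, adjusted p = 0.264). Epithelial genes (8 higher against 4.54, adjusted p = 0.151) and the endothelial and macrophage lists did not pass either. Fisher's test takes genes as independent, and camera gave the ribosomal list adjusted p = 0.417 with an estimated correlation.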

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

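The limma fit of log2(FPKM + 1), the library-size and median-of-ratios scalings in edgeR and the GC and length correction were chosen after seeing the data; the other settings were fixed before the data were examined. Values are in the order higher, lower, higher at least 2-fold and lower at least 2-fold. Restricting to mean FPKM of at least 5 gave 2893, 2848, 341 and 508 genes, since fewer genes were tested, and no filter gave 1733 and 1472 genes at 2-fold, since more were. The limma fits gave fewer genes lower by 2-fold: 409 with pseudocount 1, 642 with 0.1, 511 with 0.5, 407 without the variance trend, 404 with library weights, 485 as TPM (and 2929 lower in all) and 600 with median-of-ratios scaling (and 505 higher by 2-fold). Scaling and pseudocount each moved this count, since edgeR with library size only gave 694 and the limma count of 409 rose when either was changed alone. Camera called 21 lists, 14 in the limma fits with the 3 pseudocounts, without the trend and with weights, 13 on TPM, and 3 with an estimated correlation; why limma gave fewer was not tested. Leaving out each library gave 4207 to 4384 genes higher, 4216 to 4380 lower, 898 to 932 and 965 to 981 at 2-fold, and 20 to 22 lists.

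FTO, near 0, turned positive in limma at 0.10 with pseudocount 1, 0.13 with 0.1, 0.11 with 0.5, 0.18 as TPM, 0.10 without the trend and 0.092 with weights, and at 0.14 in edgeR with library size only; without single libraries it ranged from -0.034 to 0.015. The adjusted p of FTO over these alternatives was 0.0413 to 0.978. With median-of-ratios scaling FTO was at -0.0166 in limma and -0.00469 in edgeR, and DESeq2 gave -0.00474, so the larger positive values go with the lack of scaling for composition. ACTA2 turned to 0.10, 0.11, 0.10, 0.17, 0.10 and 0.11 in the same limma fits and 0.10 with library size only, and ranged from -0.090 to 0.019 without single libraries; its TPM value had adjusted p = 0.0156 (range over its alternatives 0.0156 to 0.860), and median-of-ratios scaling in limma gave -0.0514. As TPM, AKTIP turned to 0.019, against -0.18 with median-of-ratios scaling in limma. No list call reversed, 55 comparisons of a list with an alternative lost the call and 4 gained it, and of the other comparisons of a named gene with an alternative 2806 kept direction and side of the threshold and 40 lost the call.

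The replicate numbers did not pair the samples: same-numbered libraries correlated at -0.0103, -0.00907 and 0.0465 after group means were removed. A fit with the replicate block gave 4509, 4490, 904 and 974 genes and 21 lists. In simulated libraries of this depth the smallest planted changes were recovered only in part. That simulation changed only 50 genes at each fold, while 69.7% of tested genes were called in the real data. Its recovered shares may therefore not carry over. How far depth and library number limit what can be said of small changes here was not measured.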

Other observations

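The splits of the libraries, the trend, copy number and neighbour tests were set out before the values they measure were seen, though after the fold changes had been looked at. The tests of endoplasmic reticulum stress genes, of mesenchymal transcripts and of whole chromosomes were chosen after the result was seen, as was the search of annotation terms.

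Among 1663 biological process terms of the deposited annotation, camera at the preset correlation called 17 higher and 51 lower, and none held with an estimated correlation, where the smallest adjusted p was 0.756. The lower terms included the acute-phase response (14 of 19 genes lower, median -1.07), mitotic sister chromatid segregation (24 of 31 lower, median -0.79) and xenobiotic metabolic process (32 of 51 lower, median -0.67). The higher terms included keratinization (12 of 20 genes higher, median 0.39) and multivesicular body assembly (21 of 26 higher, median 0.40).

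With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05, and 1 of 10, the real one, gave a result as large for each count. The real split gave 4490 higher, 4479 lower, 910 and 980 at 2-fold, 21 lists and 27 Fisher calls in either direction, and the highest other split gave 0, 0, 0, 0, 14 and 0. Each other split sets 2 libraries of a group against 1, so the group difference stays in it, both between its sides and in the spread within them, and neither its 9 to 14 camera lists nor its gene counts are a chance level. In edgeR's quasi-likelihood test the other splits had at most 67 genes at an unadjusted p under 0.05, against 9232 for the real one, and no other test of single genes was run on them.

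In sh-circFTO 22 of 27 genes of the ATF4 list were lower and 3 higher, and of the serine list 17 of 25 were lower and 2 higher, a camera call lost with an estimated correlation (adjusted p = 0.0651). With the GC and length trend removed the ATF4 list kept a median of -1.47. The removed trend was weak over the tested genes (SD 0.0576 on the log2 scale), so its removal could hardly move this median. A trend of that size is too small to be the cause. Endoplasmic reticulum chaperones were split, with 11 higher and 10 lower, and had a median of 0.12 (value 0.116, 95% interval -0.255 to 0.404). The interval is a bootstrap that takes genes as independent. This argues against a general fall of that list, and other stress genes are not covered by it. In the same kind of bootstrap, 22 neighbours of ATF4 within 1 Mb had a median of -0.00586 (interval -0.242 to 0.383). That argues against a lost copy of the region. The knockdown itself, effects of the hairpin on other transcripts, culture density and the composition of the medium were not tested and stay open.

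A set of 28 genes had at most 3 counts over sh-control and rose in sh-circFTO, 5 of them protein-coding (MYH15, CCDC70, ARHGDIB, KRT13 and TFF1, the last chosen after its values were seen). Fewer genes were near 0 in sh-circFTO and fell from sh-control, RNU1-75P among them, and none of those was protein-coding. Tested neighbours of the 28 genes within 500 kb, 207 genes, had a median of 0.0660, inside the range of random sets (-0.0960 to 0.1005). This argues against a shared rise of the neighbours as a set. Activation of the region around single genes would be diluted in the pooled median and stays open. Mesenchymal cells in the cultures cannot be told apart from other sources: VIM, COL1A2 and COL3A1 rose by 0.361, 0.237 and 0.187 CPM, below the median of 0.694 CPM of the 28 genes, but COL1A1 rose by 0.938 CPM, above it, and the median of the 4 was 0.299 CPM. A clonal difference between the infected cultures could also give such genes and was not tested.

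With 69.7% of genes changed, the cultures may also differ in copy number. Medians over windows of 51 neighbouring genes had an SD of 0.132, 1.29 times the mean of 100 shuffled orders (highest 0.110), so neighbours moved together more than in any shuffled order, yet below the 1.5 times set beforehand as the sign of copy number, and regional differences cannot be told apart from shared regulation of neighbours. Chromosomes 1, 11, 14 and 19 had medians of 0.0658, 0.0856, 0.115 and 0.113, above those of random sets of as many genes (adjusted p = 0.0230 for each). No chromosome's 95% bound passed 0.209, which argues against whole-chromosome differences of 0.3 or more in all cells, while smaller ones stay open. The random sets and the bootstrap behind these bounds take genes as independent, although neighbours moved together. The p-values may therefore be too small and the bounds too narrow. After subtracting window medians 1822 genes were past the test and 2-fold, against 1890 before, with 1666 in both. The window medians were small against a 2-fold change (SD 0.132 on the log2 scale), so subtracting them could hardly move this count. Shifts of that size over such windows are too small to be the whole of the change past 2-fold. Called genes below 2-fold were not examined in this way, so the part of copy number in their change stays open.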
